A study of Homo sapiens with 2 samples.

How the data were processed

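Gene expression was measured in MDA-MB-231 cells, an established line from an invasive human breast cancer, on Illumina HumanWG-6 beadchips, 1-colour arrays on which each probe stands for 1 transcript. Per the labels' protocols, cells were transfected 2 times, 48 h apart, and RNA was taken 48 h after the later transfection. The concentration of the NSD3L siRNA was 20 nM, and that of the control siRNA was not given in the labels used here. One sample received an siRNA directed at NSD3L, the long isoform of the histone methyltransferase NSD3 (older symbol WHSC1L1), and the other a non-targeting control siRNA. There was 1 array per group, so groups, cultures, RNA extractions and arrays were the same split.

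The deposited table gave 1 linear intensity per probe and array for 48701 probes. BeadStudio is named in the submitters' processing notes. Its version, the background correction and the normalization are not given in the sources used here, and no detection p-values or bead counts were used. The authors' deposited intensities were not on a log scale and kept a background, with a lowest value of 23.8 and a most frequent value of 34.8 and 34.9 on the 2 arrays. The sorted values of the arrays were nearly the same. After sorting, the 4870 brightest values were exactly equal between the arrays, and the largest difference at any rank was 0.025 on the log2 scale, which is the pattern that quantile normalization between arrays leaves. The series description names version 3.0 of the array. The header of the probe annotation names a platform record and no version, and whether that record is of the same array version was not established. Gene names rest on the match of probe identifiers, and a mismatch of versions would bear on all of them.

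From the deposited intensities, the log2 ratio of the NSD3L siRNA array over the control siRNA array was computed for each probe with no offset and no further scaling, because the log2 medians of the arrays differed by less than 0.1. A floor was set for each array at the upper edge of its background, 2 times the mode of its intensities less their 1st percentile, which gave 40.9 for the NSD3L siRNA array and 41.0 for the control array. This rule was fixed in advance, but the estimator of the mode was not. It was taken as the peak of a kernel density of the values below the 75th percentile, chosen after the data had been opened and after a histogram peak had been looked at first. The alternative floors bracket it. The floor was passed by 18915 probes on the NSD3L siRNA array and by 18763 on the control array, and by 16489 on both. A probe above the floor on 1 array was given a bound, with the other array set to its floor. A gene was represented by its brightest probe. Of the probes, 23687 had 1 gene symbol, 35 had several and 24979 were not named by the annotation. Genes were named only from probes with 1 symbol, and symbols were updated through the gene number, which was in the RefSeq gene table for 23651 of those probes. In all, 10538 genes were above the floor on both arrays.

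With 1 array per group no test of any gene was possible and no p-values were computed. Probes and genes were counted where they differed more than 2-fold, the threshold in the series description. To describe the spread, the SD of the log2 ratio was computed over probes of similar brightness, in 10 equal groups. The SD between different probes of 1 gene was computed as well. Both describe these 2 arrays, not the spread between cultures. The number of arrays limits the precision.

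The median log2 ratio of each of 35 gene lists was set against 10000 random lists of the same size, drawn from genes above the floor on both arrays and matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the central 95% of random lists, and lists with under 5 members above the floor on both arrays got no percentile. These percentiles describe the 2 arrays and are not p-values. Local gene density, the number of other protein-coding genes within 500 kb of a gene's midpoint on either side in the GRCh38.p14 annotation, was added after the data had been seen. Random lists were also matched on density together with expression, in 5 and 10 bins.

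The gene lists, the thresholds, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule named all NSD3 probes, the 12 genes with the highest and the 12 with the lowest ratio whose probes above the floor all had the same sign, the 3 largest bounds on each array, and up to 4 members with the largest change in each list. Provisional symbols were passed over. The genes ACTB, BST2, CAV2, CCL5, CCNA2, CCNB2, CCNE2, CDC20, CDK1, CDKN1A, CKS1B, CXCL1, EIF2AK2, IDI1, MYC, NFKB1, NOP58, RPL22, TNFAIP2 and TOP2A lie outside this rule and were chosen after their values were seen. The alternatives were quantile normalization, median centring, removal of an intensity trend by lowess (span 0.3), other floors and none, an offset of 16, the mean over a gene's probes, bounds left out, thresholds of 1.5 and 3, and random lists without matching. Subtraction of each array's mode, removal of the gene density trend and density-matched lists were added later. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

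The procedure was tested on simulated data made from these 48701 probes, with a noise SD of 0.1 per array on the log2 scale. The ratios on the real arrays spread more widely, with an SD of 0.29 over probes above the floor on both, although only 0.063 among the dimmest of them. The absence of false calls in the simulation therefore gives no false call rate for the real data. The simulated changes were placed only in probes far above the floor and multiplied the whole intensity, background included. Recovery for dim probes, such as those of NSD3, was therefore not tested. All 100 simulated 3-fold changes passed the 2-fold threshold, as did 3 of 100 simulated 1.6-fold changes and 0 of 48501 unchanged probes. With simulated ratios for 10538 genes and 2000 random lists each, 5 of 100 unshifted lists of 20 genes fell outside the central 95%, and 18 of 20 lists shifted by 0.3 on the log2 scale stood above that range. These ratios were independent normal draws with the same SD for all genes, and the unshifted lists were themselves random. The share outside was thus built in, and it gives no error rate for lists of genes that are regulated together or differ in spread.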

Results

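The comparison was of 1 array of MDA-MB-231 cells transfected with the NSD3L siRNA and 1 array of cells transfected with the control siRNA. It asked which transcripts differ when the long isoform of NSD3 is targeted. NSD3 is a lysine methyltransferase that modifies histone H3. Each array held 48701 probes, and intensities ran from 23.8 to 17421 with a median of 38.4 on both. There were no replicates, so no value below has an error between cultures. Across the 16489 probes above the floor on both arrays, the log2 intensities had a Pearson correlation of 0.984 across probes, which are not independent replicates, and the log2 ratio had a median of 0.01 and an SD of 0.29.

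The targeted gene was measured first. All 3 NSD3 probes were lower on the NSD3L siRNA array, and all 3 lay near the background. The first probe annotated to the long isoform (ILMN_1807379) read 41.6 with the NSD3L siRNA and 45.0 with the control, a log2 ratio of -0.11. The other long-isoform probe (ILMN_1666715) read 37.6, below the floor, against 41.9. Its reading was at least 1.02-fold lower, a log2 bound of -0.03. The probe annotated to the short isoform (ILMN_1697919) read 40.8, below the floor, against 55.3, at least 1.35-fold lower. The SD of the log2 ratio among probes of similar brightness was 0.063 for the long-isoform probes and 0.16 for the short-isoform probe. The siRNA is described as directed at the long isoform, yet the bound for the short-isoform probe lay beyond the measured ratio of ILMN_1807379. The bounds have no upper limit, so ILMN_1666715 cannot be ranked against either. All 3 probes read too near the background to rank the isoforms or to establish depletion of the long one. The isoform of each probe was taken from its annotated transcript record, and was not checked on the probe sequence. The intensities kept their background, which draws ratios of dim probes toward 0. With the mode of each array subtracted, a setting chosen after the data were seen, the log2 ratio of ILMN_1807379 was -0.59, and the bounds for ILMN_1666715 and ILMN_1697919 were -0.20 and -1.74. The related methyltransferase genes NSD2, at 124 against 81, and NSD1, at 68 against 53, had log2 ratios of 0.62 and 0.37, that of NSD1 being 0.21 as the mean over its probes.

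More than 2-fold differences were found for 113 probes, of which 44 were higher and 69 lower with the NSD3L siRNA. The series description gives these numbers for genes, out of a smaller number of probe sets whose choice it does not state, so whether the same probes were counted is unknown. Counted as genes by their brightest probe, 36 were higher and 64 lower among 12069 genes above the floor on at least 1 array. The genes with the highest ratios were KCTD20, at 525 against 168 and 3.12-fold higher, ARL2, a small GTPase of tubulin folding, at 1782 against 581 and 3.07-fold higher, and ZNF395, at 713 against 240 and 2.97-fold higher. They were followed by FBXO27 at 2.51-fold, MAP3K6 at 2.43-fold, MVB12A at 2.41-fold, EXT1, a heparan sulfate polymerase, at 2.35-fold, SLC25A22, a mitochondrial glutamate carrier, at 2.33-fold, ATF5 at 2.32-fold, ELF4 at 2.31-fold, PLAGL2 at 2.29-fold and CSK, the kinase that restrains SRC, at 2.23-fold higher.

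The lowest ratio was that of CLDND1, a claudin-domain membrane protein, at 361 with the NSD3L siRNA against 1551 with the control, 4.30-fold lower. NXT2 was 3.22-fold lower, RGS4, a regulator of G-protein signalling, 3.21-fold, GHITM 3.05-fold and TMED5 3.04-fold lower. SCG5 was 2.85-fold lower and the histone gene H2BC21 2.83-fold lower. The neutrophil chemokine gene CXCL8 read 760 against 2149 and was 2.83-fold lower, and the cytokine gene IL24 was 2.79-fold lower. ANAPC13, a subunit of the anaphase-promoting complex, was 2.68-fold lower, FAM217B 2.68-fold and KYNU, an enzyme of tryptophan breakdown, 2.64-fold lower. Of the genes named so far from both ends, only IL24 and KYNU had a further probe above the floor on both arrays. It gave a log2 ratio of -0.42 for IL24 and -1.14 for KYNU. Among genes whose brightest probe was above the floor on 1 array alone, the bounds stayed under 2-fold. KHK, DISP2 and CATSPER2P1 were at least 1.33-fold, 1.33-fold and 1.30-fold higher, and LRRC8B, IL1RAP and PDCL3P4 at least 1.85-fold, 1.79-fold and 1.79-fold lower. Dimmer probes above the floor on both arrays gave a log2 ratio of -0.03 for LRRC8B and ratios of 0.14 and 0.01 for IL1RAP. They read 43.9 against 44.8, 46.1 against 41.8 and 43.4 against 43.1, just above the floor. There the background draws ratios toward 0, so these probes could hardly show such differences. The same draw bears on the dimmer probes of other genes named here.

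**Figure D1:**
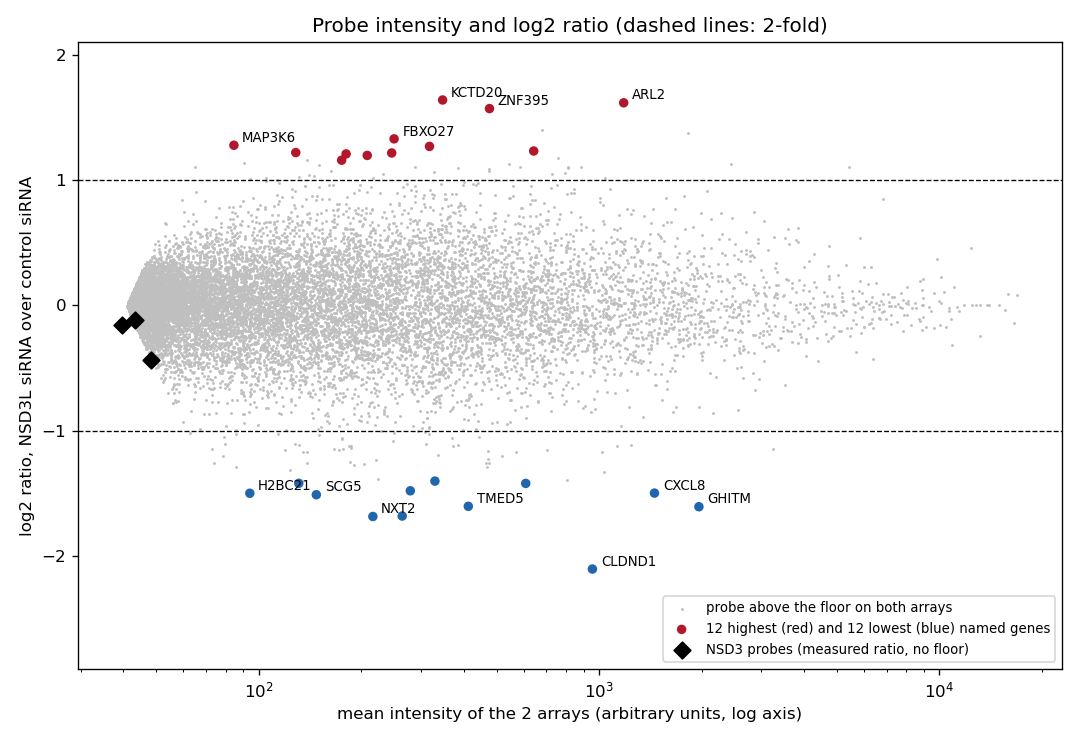
Log2 ratio of the NSD3L siRNA array over the control siRNA array against the mean intensity of the arrays (log axis, arbitrary units), 1 point per probe above the floor on both arrays, with the 12 highest and 12 lowest named genes in colour and the NSD3 probes as diamonds at their measured ratios. The named genes lie between 1.16 and 1.64 above and between -1.40 and -2.11 below, while the NSD3 probes sit at the dim end.

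Among probes with a mean intensity between 303 and 641, the SD of the log2 ratio was 0.41, and 85.3% of probes differed less than 1.5-fold. Among the dimmest probes, up to 43.8, the SD was 0.063. Their readings kept the background and had to pass the floor on both arrays, which holds ratios near 0. The smaller SD therefore does not mean that dim probes were more precise. In 288 genes with at least 2 probes brighter than 100, the SD between probes of 1 gene was 0.20. Their 2 brightest probes correlated across genes with a Pearson r of 0.74. The SD between genes was 0.38, taken over all genes with a probe that bright, also those with a single one. Over all 1016 genes with several probes, the SD within genes was 0.22, r was 0.54, and 388 genes had probes of opposite sign. Between all genes above the floor on both arrays, with a single probe or several, the SD was 0.32. The SDs within and between genes thus cover different sets of genes. Of 15 genes with several probes of which at least 1 differed more than 2-fold, only KYNU did so with every probe. ACTB, encoding beta-actin, had 3 probes with log2 ratios of 0.46, 0.85 and 1.13.

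The log2 ratio also differed with the genomic neighbourhood of the genes, compared after the data had been seen. With genes cut into 10 equal groups by gene density, the median log2 ratio was -0.11 in the group with the fewest neighbours and 0.12 in the group with the most. Spearman's rho between log2 ratio and gene density was 0.32 across 10161 genes, which are not independent replicates. The median density was 15.5 for the genes more than 2-fold higher, 8 for those more than 2-fold lower and 11 for all measured genes. For the gene lists that stood apart, percentiles are therefore also given against random lists matched on density.

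**Figure D2:**
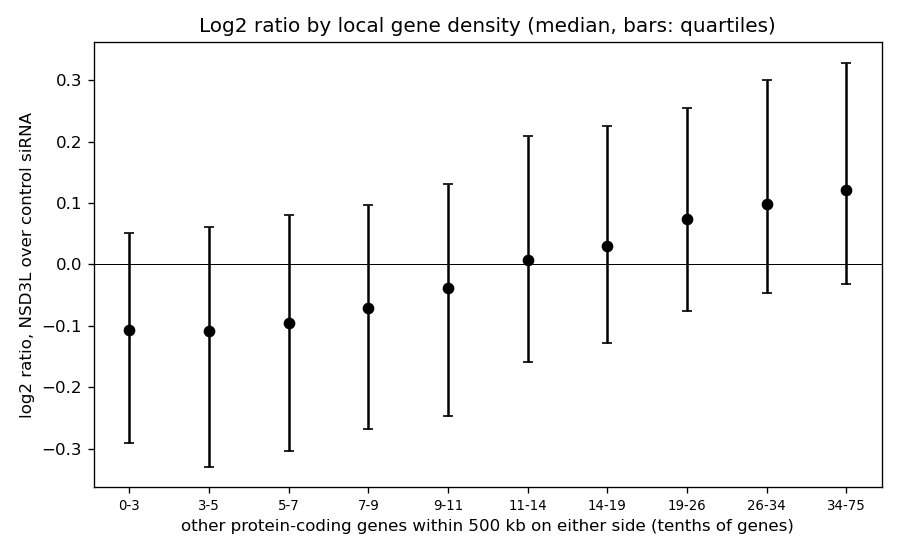
Median log2 ratio (NSD3L siRNA over control siRNA, points) and quartiles (bars) in 10 equal groups of 10161 genes by the number of other protein-coding genes within 500 kb on either side. The medians go from -0.11 in the sparsest group to 0.12 in the densest.

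Genes of cell division were higher as groups on the NSD3L siRNA array, with no member more than 2-fold higher. In the G1/S and E2F list, 20 of 23 measured genes were higher, with a median log2 ratio of 0.53. They included CDC25A, the phosphatase that activates CDK2, at 295 against 158 and a log2 ratio of 0.90, E2F2 at 0.80, CCNE1, encoding cyclin E1, at 0.78 and CCND3, encoding cyclin D3, at 0.74. CCNE2 was on the other side at -0.31. In the DNA replication list, 23 of 26 genes were higher, with a median of 0.45. The DNA polymerase gene POLE read 586 against 298 with a log2 ratio of 0.98, FEN1, the flap endonuclease, had 0.85, the helicase subunit gene MCM7 0.75 and the ligase gene LIG1 0.75. In the G2/M and mitosis list, 26 of 34 genes were higher and the median was 0.25. The mitotic kinase genes AURKB and PLK1 had log2 ratios of 0.96 and 0.77 and the checkpoint kinase gene BUB1B 0.66. The largest change in that list was a lower value, that of NEK7 at 113 against 238 and a log2 ratio of -1.07, the only member past 2-fold. It was -0.97 with an offset of 16 and -0.95 with the gene density trend removed. The medians of all 3 lists exceeded those of all 10000 random lists, at the 100th percentile, with matching on expression alone and on expression and gene density.

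The other lists that stood apart above random lists were of metabolism and the nucleolus. In the hypoxia and glycolysis list, 18 of 23 genes were higher and the median log2 ratio was 0.37, at the 100th percentile under both matchings. The aldolase gene ALDOA read 1308 against 749 with a log2 ratio of 0.80, and the phosphofructokinase genes PFKFB4 and PFKP had 0.78 and 0.68. CA12, a carbonic anhydrase gene, opposed them at -1.26. In the MYC and nucleolar list, 14 of 18 genes were higher and the median was 0.27, at the 99.7th percentile and at the 98.3rd with density matched. BOP1, of ribosome assembly, had 0.93 by its brightest probe and 0.14 by a dimmer one, SRM, the spermidine synthase gene, 0.76 and CAD, of pyrimidine synthesis, 0.54, while NOP58 had -0.51 and MYC itself -0.15. The cholesterol list had 9 higher and 7 lower genes and a median of 0.25, at the 99.4th and 99.8th percentile. SREBF2, the transcription factor of sterol synthesis, had 0.72 and LSS 0.57, while LPIN1 had -0.70 and IDI1 -0.42, so the members went both ways.

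Interferon-stimulated genes were lower on the NSD3L siRNA array, while genes of NF-kB signalling and cytokines went both ways around a lower median. Of 24 measured interferon-stimulated genes, 21 were lower, some of them only slightly, and the median log2 ratio was -0.28. It lay at the 0.04th percentile of expression-matched lists and below all lists matched on density too. IFIT2 read 586 against 1477 with a log2 ratio of -1.33, IFIT1 had -1.16, the oligoadenylate synthetase gene OAS2 -0.90, or -0.49 as the mean over its probes, and IFI44 -0.78. BST2 was higher, at 0.51. Of 20 genes of the list of NF-kB targets and inflammatory cytokines, 12 were lower and 8 higher, with a median of -0.27 at the 0.02nd percentile, again below all lists matched on density too. CXCL8 had -1.50, IL24 -1.48, the prostaglandin synthase gene PTGS2 -1.31 and IL6 -1.14. TNFAIP2 and NFKB1 were higher, at 0.52 and 0.47. The members were split, with a gap between CXCL1 at -0.44 and CCL5 at -0.10 in which the median lay. Without the floor, which adds members at background, the median was -0.10, at the 3.7th percentile, and no longer stood apart.

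The replication-dependent histones gave the lowest median, -0.71 over 9 genes, below all random lists under both matchings. H2BC21 had a log2 ratio of -1.50, H4C8 of -1.12, and the linker histone gene H1-2 read 709 against 1422, 2.01-fold lower, with a log2 ratio of -0.99 and so under 2-fold after lowess or with an offset of 16. H4C3 went the other way, at 7431 with the NSD3L siRNA against 3452 with the control and a log2 ratio of 1.11, or 0.96 with the gene density trend removed. Histone genes are close copies of one another, and whether these probes tell them apart was not tested. The list's median gene density, 47, was the highest of the 35 lists.

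**Figure D3:**
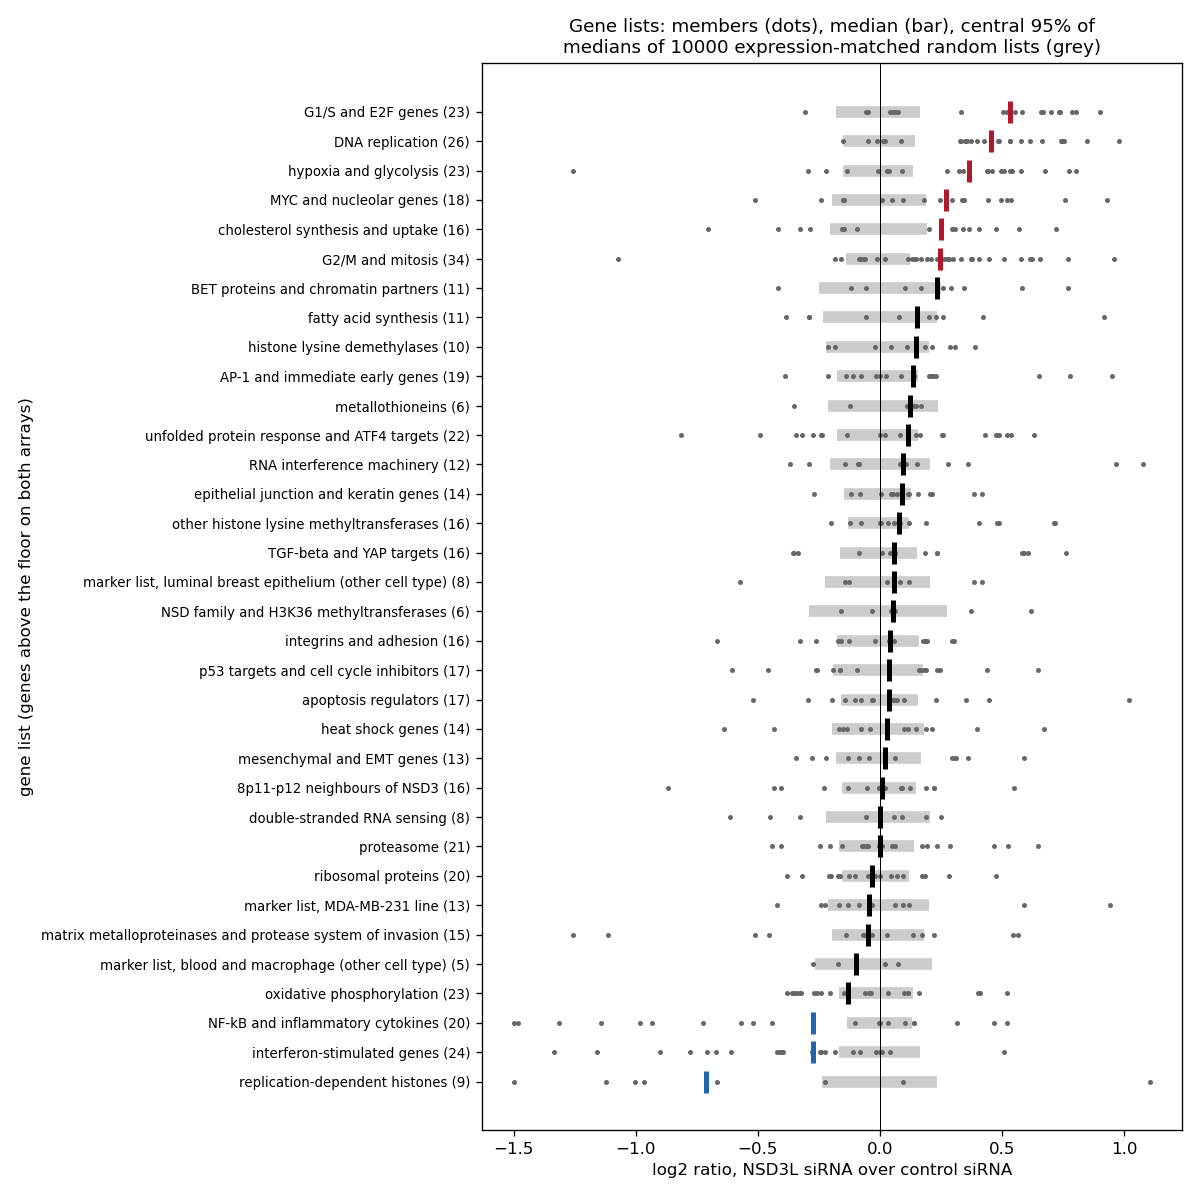
Log2 ratios of the measured members (dots) and medians (bars, red above and blue below the central 95% of random lists) of 34 gene lists, with the central 95% of medians of 10000 expression-matched random lists in grey. The G1/S list has the highest median, 0.53, and the histone list the lowest, -0.71.

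In all, 6 of the 34 lists with a percentile stood above the central 95% of random lists and 3 below it, where 1.7 of 34 lists of randomly drawn genes would fall outside. Genes within such lists can be regulated together and some lists share members, so that number is not the one expected between 2 cultures without an siRNA effect. The other 25 lists had medians between -0.13 for oxidative phosphorylation, at the 5.6th percentile, and 0.23 for BET proteins and their partners, at the 96.6th. Among them, 9 of 17 p53 targets and cell cycle inhibitors were higher and 8 lower, with a median of 0.04. CDKN1A, encoding the inhibitor p21, had a log2 ratio of 0.24. The list of matrix metalloproteinases and proteases of invasion had a median of -0.05 over 15 genes, at the 32.2nd percentile. It held MMP3 at -1.26 and MMP1, the interstitial collagenase gene, at 787 against 1703 and -1.11, with CTSB at 0.56. Mesenchymal genes had a median of 0.02 and epithelial junction and keratin genes one of 0.09. The genes around NSD3 on 8p11-p12 had a median of 0.01, with ERLIN2 at -0.87. The list of RNA interference machinery had a median of 0.10, with AGO2, the slicing Argonaute, at 644 against 305 and 1.08, and DICER1 at 0.97. BAD, a pro-apoptotic gene, had 1.02 by its brightest probe and 0.28 by a dimmer one, with a mean of 0.65, in a list of apoptosis regulators with a median of 0.04.

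Markers of other cell types showed no shift beyond random lists. The luminal breast list had a median log2 ratio of 0.06, at the 73.6th percentile, and the blood and macrophage list one of -0.10, at the 24.4th. Only 3 of 12 fibroblast markers were above the floor on both arrays, too few for a percentile. Markers of the MDA-MB-231 line had a median of -0.04 at the 40.5th percentile, and the largest differences among them were log2 ratios of 0.94 for the growth factor receptor gene EGFR, whose dimmer probe had -0.03, 0.59 for the receptor kinase gene AXL and -0.42 for MET.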

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

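The subtraction of each array's mode, the removal of the gene density trend and density-matched lists were chosen after seeing the data. Subtracting the mode gave 517 probes more than 2-fold higher and 680 lower, and 288 genes higher and 480 lower, since it enlarges ratios of dim probes and their noise, and 39 of 163 named genes moved. For NSD3 it moved the log2 ratio of ILMN_1807379 to -0.59 and the bounds for ILMN_1666715 and ILMN_1697919 to -0.20 and -1.74. The bound for ILMN_1697919 was -0.18 with the 75th percentile as floor. ILMN_1666715 had a bound of -0.13 with the median as floor and a measured ratio of -0.16 with none. These bounds depend on where the floor was put and are not measured ratios. A 1.5-fold threshold gave 465 probes higher and 499 lower and 383 genes higher and 434 lower, and a 3-fold threshold 2 and 5 probes and 2 and 5 genes. Under the 10 other alternatives run on gene counts, 28 to 39 genes were higher and 47 to 65 lower, the fewest with an offset of 16. Under the 8 others run on probe counts, 33 to 45 probes were higher and 51 to 71 lower. Quantile normalization was nearly without effect, because the deposited arrays already shared their distribution. Under 12 alternatives 6 to 8 lists stood above random lists and 2 to 3 below. Without a floor the NF-kB and cytokine list no longer stood apart, with a median of -0.10 at the 3.7th percentile, and the epithelial list did, at the 97.9th. Without matching the BET list did, at the 99th percentile, as did the immediate early genes, barely past the limit. Of 1779 ratios of named genes under alternatives, 58 moved by more than the spread of similarly bright probes, and none that was past 2-fold changed sign. With the mean over probes BAD (0.65) and IL24 (-0.95) were under 2-fold, BOP1 was 0.54 and EGFR 0.46, and IL1RAP, a bound otherwise, turned to 0.08. BAD (0.88), NEK7 (-0.97) and H1-2 (-0.99) were under 2-fold with an offset of 16, H1-2 (-0.99) also with lowess, and BAD (0.90), NEK7 (-0.95) and H4C3 (0.96) with the density trend removed. The planned search for siRNA seed matches, with its alternative of a shorter seed, was not run, because no transcript sequences were used here. No paired analysis was possible because each group had 1 array, and no array could be left out. Signal over background limits all statements on NSD3 and on other genes near the floor.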

Other observations

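The tests of a larger share of dividing cells, of a response to the control siRNA, and of brightness, RNA quality and an siRNA effect as sources of the density trend were chosen after the results they bear on were seen.

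None of the genes in this paragraph differed more than 2-fold, and their lists lay inside the central 95% of random lists. In the unfolded protein response list, with a median log2 ratio of 0.12 at the 93.0th percentile, CEBPB, a transcription factor of cytokine genes, read 1218 with the NSD3L siRNA against 2140 with the control, a log2 ratio of -0.81. In the heat shock list, with a median of 0.03, the chaperone genes HSPA1B and HSPA4 had 0.67 and -0.64. KLF6 and FOSL1 had log2 ratios of 0.95 and 0.78 in a list of immediate early genes with a median of 0.14 at the 95.8th percentile. SCD, the stearoyl-CoA desaturase gene, read 2720 against 1441 with a log2 ratio of 0.92 in the fatty acid list, whose median was 0.15 at the 88.8th percentile. In the list of TGF-beta and YAP targets, with a median of 0.06 at the 79.5th percentile, TGFBR2 had 0.76 by its brightest probe and 0.19 by a dimmer one, and ANKRD1 had 0.60.

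The rise of the log2 ratio with gene density covered genes all over the range. Its Spearman rho was 0.21 in the dimmest of 3 equal groups of genes by brightness, 0.38 in the middle group and 0.35 in the brightest, which argues against a brightness difference between dense and sparse regions as the whole cause. Without genes changed over 1.5-fold rho was still 0.30 across 9358 genes, so the trend was also present among genes that changed little. A rank correlation over so many genes gives a small set little weight, so this was a weak test of strongly changed genes as the cause. A pair of explanations, a difference in RNA quality or labelling that depends on base composition and an effect of the NSD3L siRNA on genes in gene-dense regions, cannot be told apart at a rho of 0.32, since array and siRNA were the same split.

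The higher cell cycle lists were not accounted for by that trend. The G1/S and DNA replication lists had median gene densities of 11 and 11.5, against 11 for all measured genes, so matching on density could change little. Their median log2 ratios stayed at the 100th percentile among lists matched on gene density. Density is a stand-in for base composition that may leave the composition of the probes themselves unmatched. Members contradicted by other probes of their gene were not the cause, since the G1/S median was still at the 100th percentile without its 2 such members and the DNA replication list had 0, which says nothing on members with a single probe, all but 4 of 23 and 2 of 26. A larger share of dividing cells in the NSD3L siRNA culture is a candidate explanation that the values do not settle. The G2/M list was at the 100th percentile, as that explanation requires. The replication-dependent histones were at the 0th with a median log2 ratio of -0.71. Whether their probes measure transcripts of S phase was not tested, so the histone list does not decide for or against it. Of the G2/M members 26 were higher, among them CCNA2 at 0.51, CKS1B at 0.61 and CDC20 at 0.62, and 8 were lower. CDK1 at -0.09, or 0.01 by a dimmer probe, CCNB2 at -0.07 and TOP2A at -0.01 hardly differed. A difference between 2 cultures in density or growth at harvest, unrelated to the siRNA, was not tested and stays open, as does an effect of NSD3L depletion.

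The lower interferon and cytokine lists were likewise not accounted for by gene density. Both had a median density of 15.5, against 11 for all measured genes, and the log2 ratio rose with density. The trend would thus raise their medians rather than lower them, so matching on density could not have removed the shift. The medians were at the 0th percentile of density-matched lists. An interferon and cytokine response to the control siRNA may have raised these genes on the control array. With a median log2 ratio of -0.28 for the interferon list this cannot be told apart from a lower level with the NSD3L siRNA, as no untransfected cells were compared. The concentration of the control siRNA was not given in the labels used here, so whether the doses matched is unknown. The list of double-stranded RNA sensing had 4 members higher, 4 lower and a median at the 50.6th percentile, with IFIH1 at -0.61, TLR3 at -0.45, RIGI at -0.33 and EIF2AK2 at 0.19.

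Among probes past 2-fold that the annotation did not name, 5 were higher and 2 lower. RPL22 and CAV2 each had 1 probe more than 2-fold lower, at -1.16 and -1.27, and a brighter one at -0.17 and -0.23.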
